A study of Drosophila melanogaster with 3 samples.

How the data were processed

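Micrococcal nuclease digests of S2 cell chromatin (NELF-depleted, mock-treated or untreated) were analysed from 3 files, 1 for each group. Per the labels' protocols, 200 µl of chromatin was digested with 20 units of nuclease for 45 min at 25 °C, fragments of 100 to 200 bp were purified from a gel, and paired-end reads were taken. Bowtie 0.12.3 is named in the submitters' processing notes. Its settings, the genome build, filters on duplicates and the point at which a read pair was counted are not given in the sources used here.

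The deposited values are counts: whole numbers of fragments per bin of 25 bp, not scaled by the authors to depth, with bins that hold no fragment left unlisted and taken as 0 here. The correlation between bins fell steeply within 100 bp, so a fragment was taken to be counted in 1 bin and not over its length. The file of untreated cells names its group and does not say whether it holds 1 sample alone or more. It was used as 1 library with no replicate.

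The chromosome arms in the files carry the names of release 5 of the Drosophila genome. The large arms end 0.413 to 4.17 Mb before the last gene of release 6, and chromosome 4 ends at 1.32 Mb, past the last gene of release 6 at 1.27 Mb. The gene table used here is of release 6, so its coordinates were not used and no gene, promoter or sequence motif was placed on the data. The gene lists, promoter classes and start-site profiles set out before the data were examined were therefore not run, and the comparisons that need no annotation, set out at the same time, were made in their place. DNA sequence and G+C content were not analysed here.

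Totals were 32544596 fragments for untreated, 11188903 for mock-treated and 11218731 for NELF-depleted cells. Libraries were scaled to their totals over the arms 2L, 2R, 3L, 3R and X (31423141, 10676338 and 10747076 fragments). A count of 0 in a library allows up to 3 fragments. Ratios of counts have exact 95% intervals (Clopper-Pearson, from the share of the counts of both libraries). Fragments carry no molecular identifiers, so these intervals cover counting error only. They, like the random draws below, take fragments as independent. Filters on duplicates are not given, and with duplicates both would be too narrow.

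Depleted regions were windows of 200 bp, moved in steps of 50 bp and merged, in which the untreated density was at most 0.2 of that of the surrounding 2 kb, where the surroundings had at least 0.5 of the genome mean. Their density in each library was taken relative to its own surroundings, with intervals from 1000 resamplings of blocks of 1 Mb. The surrounding 2 kb was centred on each window or region and included it. A region was thus not set against its flanks alone, least of all a wide one. Windows of 200 bp and bins of 1 kb were compared by rules of size: at least 2-fold and 50 fragments over the libraries compared for bins, and for windows at least 40 fragments over the RNAi libraries, 2-fold from mock-treated and 1.5-fold the same way from untreated cells. Windows named by position are the 10 with the largest and the 10 with the smallest ratio that passed this rule, as fixed before the data were examined. Numbers of windows and regions were set beside 100 random draws of the same depth around the trend of the RNAi ratio with untreated occupancy and, for windows, also with equal expected density in both RNAi libraries. Strong positions had at least 5 times the genome mean over 75 bp. Spacing was read from the autocorrelation over 0 to 1000 bp, taking peaks beyond 100 bp. For values of the untreated library in depleted regions, in occupancy groups and at strong positions, its fragments were divided at random (50%), and the regions, groups or positions were chosen in one part and measured in the other. Strong positions were also chosen in part of each RNAi library, a check added after the data were seen. For the ratio of NELF-depleted to mock-treated cells, depleted regions were chosen in the whole untreated library.

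The rules were tested on simulated data. For windows, all 3 simulated libraries were drawn from the rates of the untreated library, without the differences seen between mock-treated and untreated cells. Of 50 windows changed 2-fold upward for the NELF-depleted against mock-treated comparison 30 were recovered, of 50 changed 3-fold 50, of 50 changed 4-fold 50, and of 50 lowered to 0.25 of their level 24, since a lowered count can drop under the minimum. Of 194509 unchanged windows 0.425% passed. A spacing of 180 bp was read as 179 bp, and a ratio of 0.6 between the fragment counts in depleted regions as 0.600. The ratio of densities relative to the surroundings, which the results use, was not tested on simulated data.

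Alternatives covered fold, count minimum, scaling, depth, the definition of depleted regions and the library in which they were chosen. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.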

Results

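Nucleosome-protected DNA was mapped in S2 cells, a hemocyte-like line derived from Drosophila melanogaster embryos. Micrococcal nuclease cuts the linker DNA between nucleosomes, and fragments of mononucleosome size (100 to 200 bp) were sequenced from both ends. The file of untreated cells does not say whether it holds 1 sample alone or more. The 3 groups had 1 file each, used here as 1 library. They were untreated cells, mock-treated cells given double-stranded RNA against β-galactosidase, and cells given double-stranded RNA against the B and E subunits of the negative elongation factor (NELF), which holds RNA polymerase II at its pause site just downstream of the start of transcription. The mock-treated and NELF-depleted cells were harvested 96 h after the RNA was added. The libraries held 32544596 fragments for untreated cells, 11188903 for mock-treated cells and 11218731 for NELF-depleted cells, or 264, 89.7 and 90.3 fragments per kb on the 5 large chromosome arms (2L, 2R, 3L, 3R and X). With 1 library per group no difference had a replicate check and no test between groups was made. Intervals are 95% intervals within a library or between a pair of libraries and do not cover the spread between cultures, and the difference between the mock-treated and untreated libraries is given for scale. The depletion of NELF itself could not be checked, since no transcript or protein was measured here.

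The first comparison asked where nucleosome occupancy in NELF-depleted cells differed from that in mock-treated cells. Regions depleted of nucleosome-sized fragments in untreated cells held fewer fragments in the NELF-depleted than in the mock-treated library. Whether nucleosomes were absent there, or their DNA was poorly recovered or mapped, was not examined. Across 67289 such regions the density relative to the surrounding 2 kb, which includes the region, was 28.3% (28.0 to 28.7%) in NELF-depleted cells and 36.9% (36.5 to 37.3%) in mock-treated cells. The ratio between them was 0.767 (0.764 to 0.770), a log2 difference of -0.38. To measure untreated cells as well, 70543 regions were chosen in 1 random part of the untreated library and measured in the rest. There untreated cells had 15.8%, and the mock-treated density was 2.48-fold (2.45 to 2.50) above it, a larger difference than the ratio of 0.779 (0.776 to 0.782) between the RNAi libraries. The 67289 regions had a median width of 300 bp (quartiles 250 and 450 bp, longest 1600 bp) and covered 24.2 Mb, or 20.3% of the 5 arms. In 224 of them no library had a fragment. The intervals come from resampling 121 blocks of 1 Mb along the genome.

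The lower density in NELF-depleted than in mock-treated cells was seen on each of the 5 arms and in each class of region. The ratio of NELF-depleted to mock-treated density was 0.773 on 2L, 0.765 on 2R, 0.761 on 3L, 0.765 on 3R and 0.771 on X. In the regions chosen in part of the untreated library, the mock-treated density was 2.40-fold (2L) to 2.67-fold (X) that of untreated cells. Narrow regions of 200 to 250 bp had a ratio of 0.789 and regions of at least 550 bp a ratio of 0.737. With regions in 4 groups by the density of their surroundings, the ratio was 0.785 in the most sparsely and 0.754 in the most densely occupied group. In the regions chosen in part of the untreated library, mock-treated against untreated ratios went from 2.27 to 2.86 over the same widths. Around the midpoints of those 70543 regions, the lowest mean density was 0.103 of the genome mean in untreated, 0.218 in NELF-depleted and 0.302 in mock-treated cells. The flanking maxima, 375 bp from the midpoint, were 1.38, 1.31 and 1.28 times the genome mean. The maximum exceeded the minimum 13.4-fold in untreated, 6.03-fold in NELF-depleted and 4.23-fold in mock-treated cells.

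**Figure D1:**
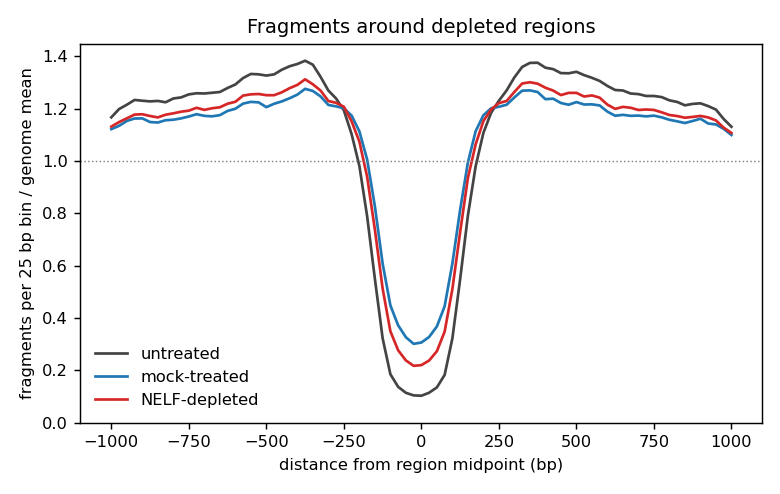
Mean fragment density per 25 bp bin, relative to the genome mean, against the distance in bp from the midpoint of 70543 depleted regions chosen in 1 random part of the untreated library, with 1 line per library (untreated: the remaining part). The lowest density was 0.103 in untreated, 0.218 in NELF-depleted and 0.302 in mock-treated cells, and the flanking maxima followed the opposite order.

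Most single depleted regions that differed between the RNAi libraries had a lower density in NELF-depleted cells. Among 33420 regions with at least 20 fragments over both RNAi libraries, 270 were at least 2-fold higher in NELF-depleted cells and 4864 at least 2-fold lower. Counts drawn 100 times around the trend shared by the regions gave a mean of 202 regions higher (177 to 238) and 4558 lower (4403 to 4734), so both observed numbers lay above the highest draw. Relative to that trend, which by itself sets the balance of directions, 1284 regions were higher (1001 to 1141 in the draws) and 1507 lower (1231 to 1443). In the regions chosen in part of the untreated library, mock-treated cells were at least 2-fold higher than untreated cells thinned to the same depth in 19623 of 27610 regions and lower in 28. These were the regions, of 70543, with at least 20 fragments over that pair. Untreated counts were low by the choice of regions, so this minimum favours regions with many mock-treated fragments. The split therefore does not describe all regions. The 5 regions with the largest ratios were picked out after their values were seen, and their intervals do not allow for that choice. On 2R, bases 11276101 to 11276350 had 18 fragments in NELF-depleted and 2 in mock-treated cells, a scaled ratio of 8.94 (2.14 to 79.5). On 3R, bases 14738501 to 14738800 had 22 and 3 fragments (7.29, 2.19 to 38.0), bases 24214451 to 24215000 had 18 and 3 (5.96, 1.74 to 31.6) and bases 893001 to 893250 had 17 and 4 (4.22, 1.38 to 17.2). On X, bases 18577301 to 18577500 had 17 and 3 fragments (5.63, 1.63 to 30.0). Coordinates are those of the files. Their genome build is not given in the sources used here, and no genes were placed on them.

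Windows of 200 bp in which the NELF-depleted library stood apart from both control libraries lay on all 5 arms. Of 224694 windows with at least 40 fragments over the RNAi libraries, 565 were at least 2-fold higher than in mock-treated and 1.5-fold higher than in untreated cells, and 471 were lower by the same rule. The intervals of single windows, here and below, cover counting error in that window alone. They do not allow for its choice as an extreme among 224694 windows. The window with the largest ratio, 3R 8850201 to 8850400, had 34 fragments in NELF-depleted and 8 in mock-treated cells, a 4.22-fold difference (1.92 to 10.6), and 33 in the deeper untreated library. Next came X 12154401 to 12154600 with 58 and 16 fragments (3.60-fold, 2.04 to 6.71), 2R 15042601 to 15042800 with 36 and 10 (3.58-fold, 1.74 to 8.08) and 2L 15206601 to 15206800 with 32 and 9 (3.53-fold, 1.65 to 8.41). The window at X 18577201 to 18577400, which overlaps a depleted region listed above, had 35 and 10 fragments (3.48-fold, 1.69 to 7.87). The remaining windows among the 10 highest were X 1655001 to 1655200, 3L 604001 to 604200, 2L 5431201 to 5431400, 2L 19327201 to 19327400 and 3R 25989401 to 25989600, with ratios from 3.38 to 3.42. In the order listed, the ratios of the 10 windows to untreated cells were 3.01, 2.42, 1.55, 1.83, 1.86, 1.51, 2.73, 3.43, 1.99 and 1.51. After scaling, mock-treated cells lay below untreated cells in each of these windows except 2L 5431201 to 5431400. The controls thus did not have equal density there.

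The largest difference in the other direction was at 2L 3796601 to 3796800, with 5 fragments in NELF-depleted, 37 in mock-treated and 32 in the deeper untreated library. The scaled ratio to mock-treated cells was 0.134 (0.0412 to 0.342) and that to untreated cells 0.457. This window was followed by 3R 3285201 to 3285400 with 9 and 42 fragments (0.213, 0.0911 to 0.444), 2R 2730001 to 2730200 with 9 and 36 (0.248, 0.105 to 0.525) and X 13842401 to 13842600 with 9 and 35 (0.255, 0.108 to 0.542). Their ratios to untreated cells were 0.627, 0.612 and 0.296. After scaling, mock-treated cells thus lay above untreated cells in each of these windows, and the controls did not have equal density. The other 6 of the 10 lowest windows, 3R 1656001 to 1656200, 2R 3677801 to 3678000, 2R 12460601 to 12460800, 3R 6866601 to 6866800, 2L 8160201 to 8160400 and 2L 19475001 to 19475200, had ratios from 0.288 to 0.320. Depleted regions touched 1 of the 10 highest and 4 of the 10 lowest windows. Of the 565 higher windows 76 touched a depleted region, of the 471 lower windows 80, and of the windows tested 13.4%.

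The higher windows exceeded by a small margin the number that counting error gives around the trend with untreated occupancy. Draws around that trend gave 475 higher windows on average (426 to 539) and 432 lower ones (385 to 494), so the higher windows exceeded the highest of 100 draws and the lower windows did not. Draws with equal expected density in the RNAi libraries gave 650 higher (579 to 713) and 772 lower windows (714 to 839), above both observed numbers, but the ratio between these libraries was not constant, going from 0.725 to 1.13 over 10 groups of windows by untreated occupancy. Among the same 224694 windows, the mock-treated library was at least 2-fold higher than NELF-depleted and 1.5-fold higher than untreated cells in 1761 and lower in 1921. Taken at least 2-fold from untreated and 1.5-fold from NELF-depleted cells, with the minimum over the pair that includes the deeper untreated library, 13759 windows were higher in mock-treated cells and 11511 lower, of 327886. With mock-treated counts corrected for the trend, 777 windows were higher and 723 lower by the first rule. With the untreated library left out, 2487 windows were at least 2-fold higher in NELF-depleted than in mock-treated cells and 2255 lower.

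The difference between the RNAi libraries changed steadily with how occupied a window was in untreated cells. Windows were put in 10 groups by their count in 1 random part of the untreated library, and their densities were measured in the other part and in the RNAi libraries. In the lowest group the density was 0.0985 of the genome mean in untreated, 0.202 in NELF-depleted and 0.278 in mock-treated cells, a ratio of NELF-depleted to mock-treated of 0.725. In the highest group it was 3.70, 2.72 and 2.42, a ratio of 1.13. The RNAi libraries had equal density near the seventh group, with a ratio of 1.01. The ratio of mock-treated to untreated density went the other way, from 2.83 in the lowest to 0.653 in the highest group.

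**Figure D2:**
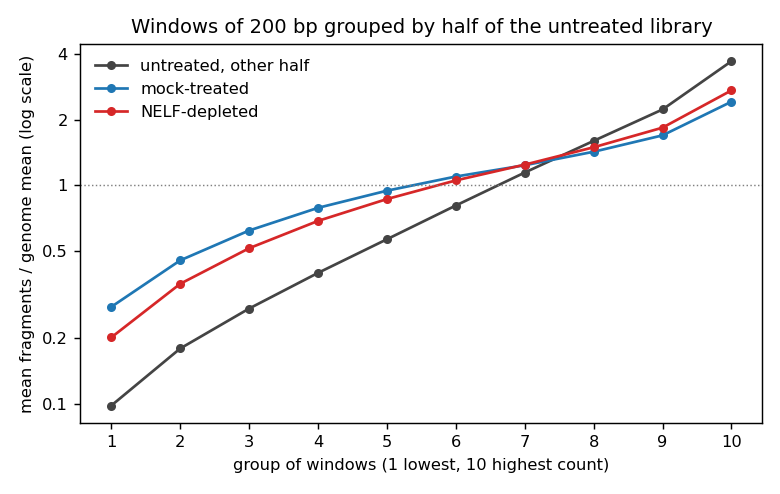
Mean fragment density relative to the genome mean (log scale) in 10 groups of 200 bp windows ordered by their count in 1 random part of the untreated library, with 1 line for each library. From the lowest to the highest group the density went from 0.0985 to 3.70 in untreated, 0.202 to 2.72 in NELF-depleted and 0.278 to 2.42 in mock-treated cells.

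Over longer stretches the RNAi libraries were close to each other. Across bins of 1 kb on the 5 arms, Pearson's r between NELF-depleted and mock-treated cells was 0.963 and Spearman's rho 0.942, against 0.875 and 0.854 between mock-treated and untreated cells (bins are not independent replicates). Of 109542 bins with at least 50 fragments, 15 were at least 2-fold higher in NELF-depleted than in mock-treated cells and 403 at least 2-fold lower. Between mock-treated and untreated cells 14303 of 111252 bins were higher (12.9%) and 1249 lower (1.12%). Between NELF-depleted and untreated cells 7209 of 110808 were higher and 434 lower. The median bin lay 0.15 above 0 on the log2 scale for mock-treated against untreated and 0.12 for NELF-depleted against untreated cells. Relative to that median, the numbers were 10040 higher and 2880 lower for mock-treated and 4407 higher and 923 lower for NELF-depleted cells.

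Chromosome 4, a small chromosome rich in heterochromatin, and the separately assembled heterochromatin arms differed more between the libraries than the large arms did. Scaled to the 5 large arms, chromosome 4 had 0.828 (0.819 to 0.838) times as many fragments in NELF-depleted as in mock-treated cells, and the 5 heterochromatin arms other than that of Y together had 0.918 times as many (0.913 to 0.923). Against untreated cells, the mock-treated library had 1.93 (1.91 to 1.95) times as many fragments on chromosome 4 and 1.39 (1.39 to 1.40) times as many on the heterochromatin arms. All 13 pieces of 100 kb on chromosome 4 were lower in NELF-depleted than in mock-treated cells, with a median log2 ratio of -0.28 and an SD of 0.055 over pieces. On the large arms 1186 pieces had a median of 0.00 with an SD of 0.061. The X arm, in contrast, had 1.02 times as many fragments in NELF-depleted as in mock-treated cells and 0.898 times as many in mock-treated as in untreated cells.

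On the large arms, nucleosome spacing differed between the libraries by less than the bin of 25 bp. The autocorrelation of fragment positions had its first peak at 172.8 bp in untreated, 174.8 bp in mock-treated and 174.6 bp in NELF-depleted cells, the second at 342, 347 and 345 bp and the third at 518, 536 and 535 bp. Arm by arm, the first peak of NELF-depleted cells lay -0.141 ± 0.216 bp (SD over 5 arms) from that of mock-treated cells and was later on 1 arm, and the second peak lay -1.97 ± 0.278 bp from it and was later on 0 arms. Mock-treated cells had a later first peak than untreated cells on 5 of 5 arms, by 1.91 ± 0.556 bp. The distance from the first to the second peak was longer than in untreated cells on 4 of 5 arms in each RNAi library, by 4.26 ± 4.29 bp in mock-treated and 2.43 ± 4.35 bp in NELF-depleted cells, a mean within the spread between arms, and it was shorter on 3L. The repeat length from the first to the third peak, which rests on the third peak, was longer on 5 of 5 arms, by 6.94 ± 1.99 bp and 5.87 ± 2.62 bp. The first peak stood 0.171 above the following trough in untreated, 0.168 in mock-treated and 0.176 in NELF-depleted cells. On chromosome 4 the first peak lay at 173, 176 and 175 bp in untreated, mock-treated and NELF-depleted cells, but the third was read at 698, 524 and 516 bp. For the heterochromatin arms the first peak was read at 170, 529 and 166 bp in the same order. Peaks were thus not read reliably off the large arms. Shifting one library along the other gave the highest correlation at a lag of 0 bp in each of the 3 pairs, in steps of 25 bp.

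**Figure D3:**
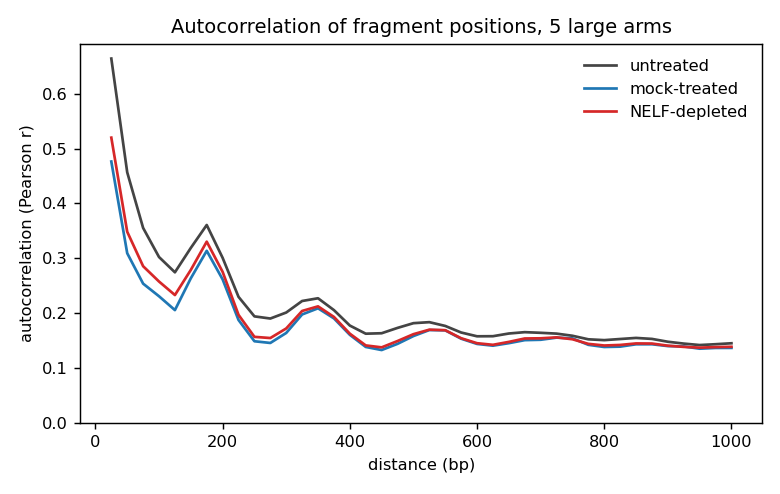
Autocorrelation (Pearson's r) of fragment counts in 25 bp bins on the 5 large arms against distance in bp, with 1 line for each library. The first peaks lie at 172.8, 174.8 and 174.6 bp for untreated, mock-treated and NELF-depleted cells.

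The mean profile over strong nucleosome positions of untreated cells peaked at the same place in the RNAi libraries, at lower height. These positions were chosen by height, and their surroundings were raised as well. At 1000 bp before them the density was 1.85 times the genome mean in untreated, 1.67 times in NELF-depleted and 1.60 times in mock-treated cells. At 40728 positions chosen in 1 random part of the untreated library, the density in the central bin was 7.62 times the genome mean in the rest of that library, 5.06 times in NELF-depleted and 4.49 times in mock-treated cells. The central 75 bp held 45.5% of the fragments of a 325 bp stretch around the position in untreated, 41.1% in NELF-depleted and 40.6% (40.5 to 40.7%) in mock-treated cells, against 23.1% for an even distribution. The neighbouring nucleosome appeared 175 bp away in each library, with a density of 3.29, 2.71 and 2.54 times the genome mean in the same order. The order of heights was the same where positions were chosen in part of an RNAi library and that library was measured in the rest. At 17049 positions from the mock-treated library the central density was 7.59 in untreated, 6.29 in NELF-depleted and 5.76 in mock-treated cells, and at 23945 positions from the NELF-depleted library it was 7.28, 5.88 and 5.23.

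**Figure D4:**
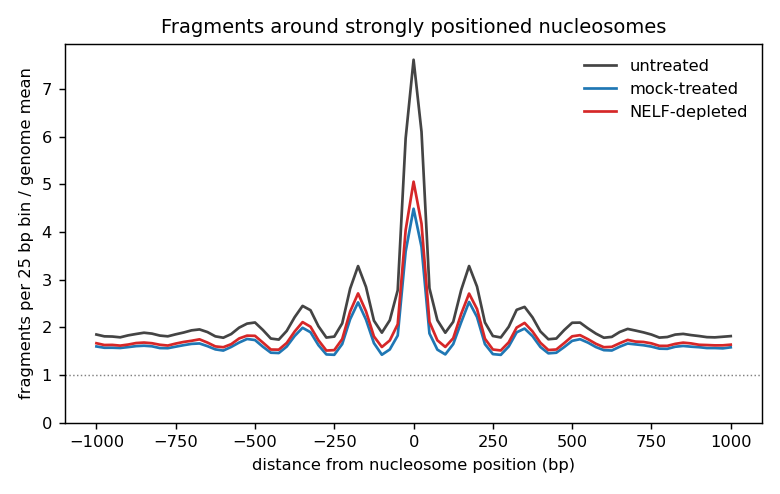
Mean fragment density relative to the genome mean against the distance in bp from 40728 strong nucleosome positions, chosen by height in 1 random part of the untreated library, with 1 line for each library (untreated: the remaining part). The central density was 7.62 in untreated, 5.06 in NELF-depleted and 4.49 in mock-treated cells, and the neighbouring peaks lay at 175 bp in each.

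The comparison of mock-treated with untreated cells served as a measure of how far libraries differed without NELF depletion, and it also held the RNAi treatment. Growth conditions are described for S2 cells from 2 sources in different media, and the RNAi cells came from one of them. The labels do not say which was used for the untreated library. Depleted regions, chromosome 4 and the heterochromatin arms had more fragments in mock-treated than in untreated cells, and well-occupied windows, strong positions and the X arm had fewer. NELF-depleted cells lay between the control libraries in depleted regions, at strong positions, on chromosome 4, on X and on the heterochromatin arms. For depleted regions chosen in part of the untreated library and measured in the rest, the ratio of NELF-depleted to untreated cells was 1.93 (1.91 to 1.95), and for chromosome 4 it was 1.60 (1.58 to 1.62).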

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

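Chosen after the data were seen were the depth-matched 1 kb bins, leaving out empty regions, scaling regions to the arms, regions from random parts of each library or measured in the whole untreated library they came from, the trend-corrected mock counts and leaving out the untreated library. Of 46 alternatives 20 left a value within its bounds (1.5-fold for a number of bins or windows) and 26 moved it. Numbers of bins or windows and spacing peaks have no direction, so only depleted-region ratios could be reversed, and 0 were. The ratios counted as moved lay outside the interval of the main ratio (0.764 to 0.770 against mock-treated, 1.91 to 1.95 against untreated cells). Capping the highest counts put the first spacing peaks at 173.2 (untreated), 175.2 (mock-treated) and 175.0 bp (NELF-depleted), counted as not moved. At 1.5-fold, 1 kb bins higher and lower numbered 956 and 4214 for NELF-depleted against mock-treated, 30520 and 9458 for mock-treated against untreated, and 23484 and 5283 for NELF-depleted against untreated cells. With at least 100 fragments, NELF-depleted against mock-treated gave 4 and 52, and 4521 were higher than in untreated cells. Scaling to the median ratio gave 2880 bins lower in mock-treated than untreated cells, and 4407 higher and 923 lower in NELF-depleted than untreated cells. The depleted-region ratio was 0.705 for regions at most 0.1 of their surroundings and 0.763 for windows of 150 bp. With regions chosen in 1 random part of a library it was 0.779 (untreated), 0.809 (mock-treated) and 0.779 (NELF-depleted). The ratio of NELF-depleted to untreated cells, 1.93 in regions chosen in part of the untreated library and measured in the rest, was 1.60 in regions from the mock-treated library and 2.26 in regions chosen and measured in the whole untreated library. Windows higher and lower numbered 25 and 17 at 3-fold, 7 and 7 with at least 80 fragments, and 2487 and 2255 without the untreated library. Trend-corrected mock counts gave 777 higher, within the bounds, and 723 lower. Except where the rule itself was stricter or looser, the cause was not tested. Promoter, gene-list, motif and G+C alternatives were not run. No paired analysis was possible because each group has 1 file, used as 1 library. Of simulated 2-fold rises in windows 60% were recovered. These rises lay on the 2-fold cut of the rule, so that share says little about what this depth allows. Of 50 simulated 3-fold rises 50 were recovered. The simulation held no difference between mock-treated and untreated cells, so recovery in the real libraries can differ from this.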

Other observations

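The tests of counting error, of an effect at depleted regions alone and of a deviation of the mock-treated library alone were chosen after the results were seen. Long stretches of the genome had a high fragment density in all 3 libraries. Of 1188 pieces of 100 kb, 90 had at least 1.5 times the median of their arm in each library, and they formed 46 segments, with 32 of the pieces on 3L and 22 on X. The longest was 3L 500001 to 2000000, a stretch of 1500 kb with 2.68 times the arm's median in untreated, 2.34 times in mock-treated and 2.43 times in NELF-depleted cells. On X, bases 1700001 to 2400000 had 1.99 times the median in untreated and in NELF-depleted cells, and bases 5500001 to 6000000 had 2.93 times in untreated, 2.28 times in mock-treated and 2.31 times in NELF-depleted cells. The density of X relative to the large autosome arms was 0.768 in untreated, 0.677 in mock-treated and 0.693 in NELF-depleted cells, and that of chromosome 4 was 0.279, 0.530 and 0.440. The fullest bin of each library lay on 3L, at base 24458151 with 2054 fragments in untreated cells and at base 24458326 with 723 in mock-treated and 752 in NELF-depleted cells.

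The contrast between depleted regions and their surroundings was greatest in untreated, lower in NELF-depleted and least in mock-treated cells. To test the depth of the untreated library, part of it was thinned to the mock-treated total and measured in regions chosen in the rest. It had 0.404 times the mock-treated density (15.8% against 39.1%). Random thinning leaves that expected density unchanged, so this could not test how depth affects the choice of regions. In regions chosen in part of the shallower mock-treated library, untreated cells had 15.7% and mock-treated cells 28.7%, which argues against depth as the cause. An effect of NELF depletion at depleted regions alone was tested in windows outside them. There the ratio of NELF-depleted to mock-treated density differed by 0.296 between the lowest and highest of 4 occupancy groups (0.819 and 1.11). The sparsest of these windows had 0.0531 of the genome mean in untreated cells, so that gap cannot separate depleted regions from other sparse sites. From windows with 1.12 to those with 3.75 times the genome mean, the ratio still went from 1.01 to 1.13. That argues against an effect at sparse sites alone. A candidate explanation is a difference in recovery along 1 axis shared across the genome, such as the extent of digestion, since the slope of log2(NELF-depleted/mock-treated) on log2(untreated/mock-treated) was 0.204 (0.196 to 0.211) over 38840 bins of 1 kb without a depleted region, with different random parts of the mock-treated library on each side; a deviation of that library alone would give such a slope too, but would not put NELF-depleted cells between the controls, and with parts of the NELF-depleted library on each side the slope was -0.239 (-0.249 to -0.230). Genome-wide effects of NELF depletion or RNAi and a different source of untreated cells stay open as untested, and G+C content was not analysed here.

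More depleted regions differed between the RNAi libraries, and more windows were higher in NELF-depleted cells, than counting error around the shared trend gave. Of these regions 270 were at least 2-fold higher in NELF-depleted cells, against 238 in the highest of 100 draws, and the excess went both ways, with 4864 lower regions against 4734 in the highest draw. For 200 bp windows, 565 were higher, against 539 in the highest draw around the trend, while the 471 lower ones lay within the draws. Depleted regions held 76 of the higher windows, within the 71 to 111 of those draws. NELF depletion at some sites and spread between library preparations beyond counting error are both open as hypotheses, since no replicate gives that spread. The draws also take fragments as independent, and duplicates were not examined.

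Chromosome 4 took 0.599% of fragments in mock-treated and 0.314% in untreated cells. The trend with occupancy on the large arms could account for part of this: mock-treated counts on chromosome 4 were 1.19 times those expected from its untreated counts and that trend. The value lay above the 1.1 set beforehand for the trend as the whole cause and below the 1.2 set for excluding it, and the arms themselves ranged from 0.838 on X to 1.04 on 2L. The trend and a true difference in the share of chromosome 4, for example in copy number between cultures, cannot be told apart here, since the value lies between those bounds. On the heterochromatin arms the observed counts were 1.01 times those expected.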
